A study of Mus musculus with 47 samples.

How the data were processed

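Gene expression was measured in mouse lung with Affymetrix murine U74 arrays. Per the labels, mice were sensitized on days 0 and 3, challenged through the trachea on days 10 and 17, and killed 24 h or 72 h later. Sensitization and challenge used ragweed pollen protein, with alum as adjuvant at sensitization, or PBS. The labels name alum for ragweed alone, so whether the PBS mice received it is not known. The 4 groups hold 2 samples each, coded 1a and 1b: PBS at 24 h, ragweed at 24 h, PBS at 72 h and ragweed at 72 h. The labels do not say whether 1a and 1b are separate animals, so the p-values measure the spread between these samples, which may be technical. The array set has an A, a B and a C array, each in a first version and a version 2, which gives 6 tables. The version 2 A table has no ragweed arrays of 24 h among those analysed here.

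The deposited values are linear intensity, 1 value per probe set and array. What software the authors used before that step is not given in the sources used here. All version 2 arrays, and the first-version ragweed arrays, had been scaled by the authors to a 2% trimmed mean of about 800. The first-version PBS arrays had not: their trimmed means ran from 80.6 to 376.5. An additional first-version A array of ragweed at 24 h, without a letter in its code, equalled the 1a array divided by 2.63 at every probe set, and was counted as the same array. The series therefore holds 46 distinct arrays out of 47.

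The comparisons used the first-version A table, which has all 4 groups, restricted to the 9977 probe set IDs that are also on version 2 A, and the version 2 B and C tables. Version 2 B and C kept the deposited scale. The first-version A arrays were scaled to a trimmed mean of 800 and quantile normalized on the log2 scale. A floor was then set at the 40th percentile of each table, an intensity of 291.6 for A, 356.4 for B and 244.7 for C, and lower values were raised to it. Flooring before scaling had been planned, but on the unscaled PBS arrays it would have raised most values to the floor, so the order was changed after the data were seen. Between 56.4 and 60.7% of the values of an array lay above the floor on version 2 B and C, and between 58.8 and 59.5% on first-version A. Probe sets above the floor on at least 2 arrays of their table were tested: 6896 on A, 9190 on B and 9164 on C, 25250 in all. Replicate arrays correlated across probe sets with r from 0.947 to 0.960 on A, from 0.858 to 0.926 on B and from 0.781 to 0.927 on C, the lowest being the ragweed 24 h pair on C. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.23 on A, 0.32 on B and 0.45 on C.

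Each table was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over the 8 samples, 4 residual degrees of freedom and eBayes with a mean-variance trend. The contrasts were ragweed against PBS at 24 h, the same at 72 h, the mean of both, the difference between them (72 h minus 24 h), and PBS at 72 h against PBS at 24 h. Within each contrast the p-values of the 3 tables were pooled and adjusted by Benjamini-Hochberg, and probe sets with an adjusted p under 0.05 were called. Errors given with ± are standard errors of the log2 difference, with n = 2 samples per group unless more are named. An SE given with a list median is computed over the genes of the list, which are not independent replicates. Where all samples of the lower group lay at the floor and all of the higher group above it, the difference is a lower bound and is given as "at least". A difference between the times built from groups at the floor is given as fitted, whether or not it is a bound. Values raised to the floor are equal and add no spread, though their samples count in the degrees of freedom. Standard errors and p-values of probe sets with a group at the floor may therefore be too small.

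Gene symbols came from the array annotation, updated by gene ID. For gene counts and lists, 1 probe set with a single symbol stood for each of 12840 genes, A before B before C and then the brightest. Probe sets matched to more than 1 gene are given by ID. No genome positions are given, since the sources used here state no build for the arrays. The genes to be named were set by rule: the 12 genes with the largest rise and the 8 with the largest fall at each time among called genes whose ragweed samples both lay beyond both PBS samples, the 8 called genes with the largest difference between the times, the 5 largest in each direction between the PBS times, up to 4 members of each gene list, and a fixed set of genes of the allergic response with their values whether called or not. Where no probe set of such a gene was tested on the 3 tables, its 72 h value on version 2 A is given. The 38 gene lists were tested with camera (limma) with a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg over the 37 lists with at least 3 measured genes. Thymocyte markers, with fewer, were not tested. The tables, contrasts, rule, these lists and most alternatives were fixed before the data were examined. The squamous epithelium and NRF2 target lists used later are not among these lists.

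The procedure was tested on simulated data in 10 rounds with the same design. Of 50 probe sets shifted 4-fold per round, 22% were called for 24 h and 21% for 72 h. At 8-fold these shares were 34.4% and 35.2%, and at 2-fold 3% and 2.4%. False calls averaged 2 per round for 24 h (6.27% of calls) and 0.7 for 72 h (2.33%). A list shifted 2-fold passed in 10 of 10 rounds for each time. Each probe set was drawn independently, so the rounds do not show how the list test behaves when genes vary together. Most of the simulated changes were thus missed, even at 8-fold, so a gene that was not called may still have changed.

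Alternatives covered the array version, floor, filter, offset, normalization, variance trend, replicate block, adjustment within tables and leaving out each sample. Added after the data were seen were the planned order of flooring, the first-version A table alone, leaving out the C table, and using the PBS samples of both times or of the other time. The first-version B and C tables are used for the repeat of effects and the alternative with the other array version. The version 2 A table is used for these, for genes not tested elsewhere and for marker lists. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.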

Results

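Gene expression was measured in the lungs of mice that had been sensitized to ragweed pollen protein and challenged with it through the trachea, and of mice given PBS in its place. The labels name alum, the adjuvant at sensitization, for the ragweed mice alone, so the differences between ragweed and PBS may include an effect of alum. Lungs were taken 24 h or 72 h after the last challenge, and each of the 4 groups had 2 samples. Every sample was measured on A, B and C arrays of the murine U74 set, and most of the A arrays were run in both array versions. The values are array intensities, and the number of arrays limits their precision. The comparisons below ask how the lung's gene expression differed between ragweed and PBS at each time, whether that response differed between the times, and how the PBS groups differed from each other.

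At 24 h the ragweed lungs had higher levels of alternatively activated macrophage genes, of eosinophil and T helper 2 chemokines and of mucus genes than the PBS lungs. Chil3 (92694_at), a chitinase-like protein of alternatively activated macrophages, rose 30.3-fold, from a mean intensity of 1544 to 46647 (log2 difference 4.92 ± 0.12, adjusted p = 2.7e-06). Its ragweed values of 43673 and 49622 were near the top of the array, where the normalization sets values by rank. The size and error of its difference are therefore uncertain. Ccl8 (92459_at), a chemokine that attracts T helper 2 cells through the receptor Ccr8, rose from the floor to 4939, a log2 difference of at least 4.05 ± 0.28 (adjusted p = 5.93e-04). Muc5b (165954_f_at), a gel-forming mucin of the airway, rose by 3.83 ± 0.18 (adjusted p = 8.36e-05), and Retnla (162835_at), a secreted product of alternatively activated macrophages, by 3.70 ± 0.25 (adjusted p = 8.36e-05). Mmp12 (95339_r_at), the macrophage elastase, rose by 3.52 ± 0.23 (adjusted p = 5.03e-04). Of 25250 probe sets tested, 58 were called, 53 higher and 5 lower in ragweed, and 2190 had an unadjusted p under 0.05. The called probe sets gave 42 genes that rose and 5 that fell.

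Other large rises at 24 h were in single genes of several kinds. Bpifb1 (167154_f_at), a secreted protein of mucous cells, rose by 3.41 ± 0.22 (adjusted p = 3.79e-04), and Fcgbp (97826_at), a mucus protein that binds the Fc part of IgG, by 2.89 ± 0.16 (adjusted p = 2.06e-04). Agr2 (101075_f_at), a protein disulfide isomerase needed for mucin folding, rose by 2.61 ± 0.26 (adjusted p = 0.00528). Reg3g, an antimicrobial lectin, rose by 3.01 ± 0.19 (adjusted p = 3.79e-04). Fxyd4, a regulator of the sodium pump, rose by 3.07 ± 0.32 (adjusted p = 0.00148), Slc5a1, a sodium-glucose transporter, by 2.97 ± 0.50 (adjusted p = 0.0396), and Fer1l6, a member of the ferlin family, by at least 4.21 ± 0.40 (adjusted p = 0.00377). The 5 genes that fell were Srxn1, which reduces oxidized peroxiredoxins (-1.35 ± 0.18, adjusted p = 0.0282), Hspd1, a mitochondrial chaperone (-1.31 ± 0.17, adjusted p = 0.0306), Cpm, a membrane carboxypeptidase (-1.10 ± 0.18, adjusted p = 0.0396), Krt19, a keratin of simple epithelium (-0.86 ± 0.11, adjusted p = 0.0243), and Sqstm1, an autophagy receptor (-0.81 ± 0.10, adjusted p = 0.0199).

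Among 37 gene lists tested, 10 passed at 24 h, all upward, and 7 of them passed with an estimated correlation. Of 13 mucous and goblet cell genes measured, 6 rose and none fell, with 10 higher when adjusted over the list alone (median log2 difference 0.96, list adjusted p = 3.37e-15). Of 14 alternatively activated macrophage genes, 4 rose, with 6 higher when adjusted over the list alone (list adjusted p = 1.90e-10). They included Arg1, the arginine-degrading enzyme of these macrophages, at least 2.41 ± 0.25 higher. Of 10 eosinophil and T helper 2 chemokines, 4 rose, with 6 higher when adjusted over the list alone (list adjusted p = 7.43e-08). Besides Ccl8 these were Ccl11 and Ccl24, the eotaxins, which rose by 2.49 ± 0.30 and at least 2.36 ± 0.40, and Ccl9, a chemokine for myeloid cells, which rose by 2.46 ± 0.32. Of 17 lysosomal proteases and hydrolases, 2 rose, with 3 higher when adjusted over the list alone (list adjusted p = 5.82e-06): Ctss by 0.92 ± 0.09 and Ctsb by 0.68 ± 0.09, both cathepsins. Of 12 acute phase proteins and protease inhibitors, 1 rose, Saa3, an acute phase apolipoprotein, by 1.66 ± 0.12, with 5 higher when adjusted over the list alone (list adjusted p = 1.72e-06). Of 11 MHC class II genes, 1 rose, H2-DMb1, a peptide-loading chaperone, by 1.24 ± 0.17, with 2 higher when adjusted over the list alone (list adjusted p = 1.98e-05).

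Of 17 B cell and plasma cell markers, 2 rose at 24 h, with 3 higher when adjusted over the list alone (list adjusted p = 0.00537; adjusted p = 0.138 with an estimated correlation). They were Jchain, which joins IgA and IgM chains, by at least 2.07 ± 0.17, and Ighm, the IgM heavy chain, by 1.68 ± 0.12, where 5 of its 12 probe sets went the same way. Pigr, which carries IgA across epithelium, rose by 1.79 ± 0.10 and was the riser among 8 Fc and immunoglobulin receptors, 2 of which were higher when adjusted over the list alone (list adjusted p = 0.00862; adjusted p = 0.138 with an estimated correlation). Of 13 complement genes, C1qa, a chain of the first complement component, rose by 0.86 ± 0.11, with 3 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.00924; adjusted p = 0.301 with an estimated correlation). Without the ragweed 24 h 1b sample the list adjusted p was 0.120 for complement and 0.0589 for the Fc receptors.

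Of 9 club cell markers, 3 rose at 24 h, with 7 higher when adjusted over the list alone (median 0.90, list adjusted p = 2.59e-10). Scgb1a1, the main secretoglobin of club cells, rose by 1.27 ± 0.12 and Cyp2f2, their cytochrome P450, by 0.65 ± 0.09. These rises depended on the reference: against the PBS samples of 72 h the difference was 0.00 for Scgb1a1 and -1.03 for Cyp2f2, and the list went downward (adjusted p = 0.689). The same change of reference gave 0.03 for Srxn1, 0.03 for Krt19, 0.18 for Sqstm1, -0.26 for Hspd1 and -0.01 for H2-DMb1, none called. C1qa (0.44), Slc5a1 (2.17) and Ccl24 (2.09) were not called there either, while Cpm (-1.68) was. Muc5b, Mmp12 and Fcgbp were still called, at 1.86, 1.90 and 1.54. The list adjusted p there was 0.747 for MHC class II and 0.981 for B cell and plasma cell markers, both downward. For complement it was 0.689, for the Fc receptors 0.0788 and for acute phase 0.0547, all upward. Against the PBS samples of both times the list adjusted p was 0.118 for B and plasma cells, 0.0522 for MHC class II and 0.0968 for complement. With the other array version it was 0.0502 for B and plasma cells. Ciliated cell markers, which share the airway lining with club cells, did not pass (6 measured, list adjusted p = 0.706), nor did alveolar type II cell markers (14 measured, median -0.03, mean and test upward, list adjusted p = 0.900). Scgb1a1 ranked 16 and 18 by intensity in PBS at 24 h and 1 or 2 in the other groups, where the normalization sets its value, 75777 both in ragweed at 24 h and in PBS at 72 h. Sftpc ranked 2 to 6 on each first-version A array, so its values there are set in the same way.

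Few genes of type 2 cytokine signalling itself were called at 24 h. Of 9 type 2 cytokines, receptors and transcription factors, 1 rose, Il33, an epithelial alarmin, by 1.26 ± 0.21 (adjusted p = 0.0373), and the list did not pass (adjusted p = 0.487; median -0.09, mean and test upward). Il5, with 1 of its 4 values above the floor, differed by -0.09, Il4ra by 0.28, Ccl22 by 0.05, Itln1 by 0.96 (adjusted p = 0.239), Clca1 by -0.37 (adjusted p = 0.724) and Sftpc by -0.27 (adjusted p = 0.609). The mast cell protease Mcpt1 was at the floor in both 24 h groups. Il4, Il13, Il13ra2, Ccl17, Cpa3 and Prg2 were on the arrays but had no probe set that was tested. Markers of eosinophils (3 measured, list adjusted p = 0.519), mast cells (8, 0.487), T cells (12, 0.794), neutrophils (8, 0.260), and macrophages and monocytes (14; adjusted p = 0.391 with an estimated correlation) did not pass.

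The 24 h counts depended on single samples. Leaving out 1 sample gave 32 (PBS 24 h 1a), 26 (PBS 24 h 1b), 204 (ragweed 24 h 1a), 98 (ragweed 24 h 1b), 32 and 32 (PBS 72 h) and 22 and 22 (ragweed 72 h) called probe sets. Of the 34 called genes named for 24 h, 13 passed in every one of these fits: Chil3, Ccl8, Muc5b, Retnla, Mmp12, Bpifb1, Reg3g, Fcgbp, Jchain, Ighm, Saa3, Pigr and Acta1, and all 34 kept their direction. Against the PBS samples of 72 h, 3 of these 13 were not called: Jchain (0.08), Ighm (0.44) and Acta1 (-0.30). Of the 34, 21 were still called in the same direction against that reference, Cyp2f2 was called in the opposite one and 12 were not called. The kept direction of the 34 in the fits without 1 sample was largely fixed by their choice and is no support.

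**Figure D1:**
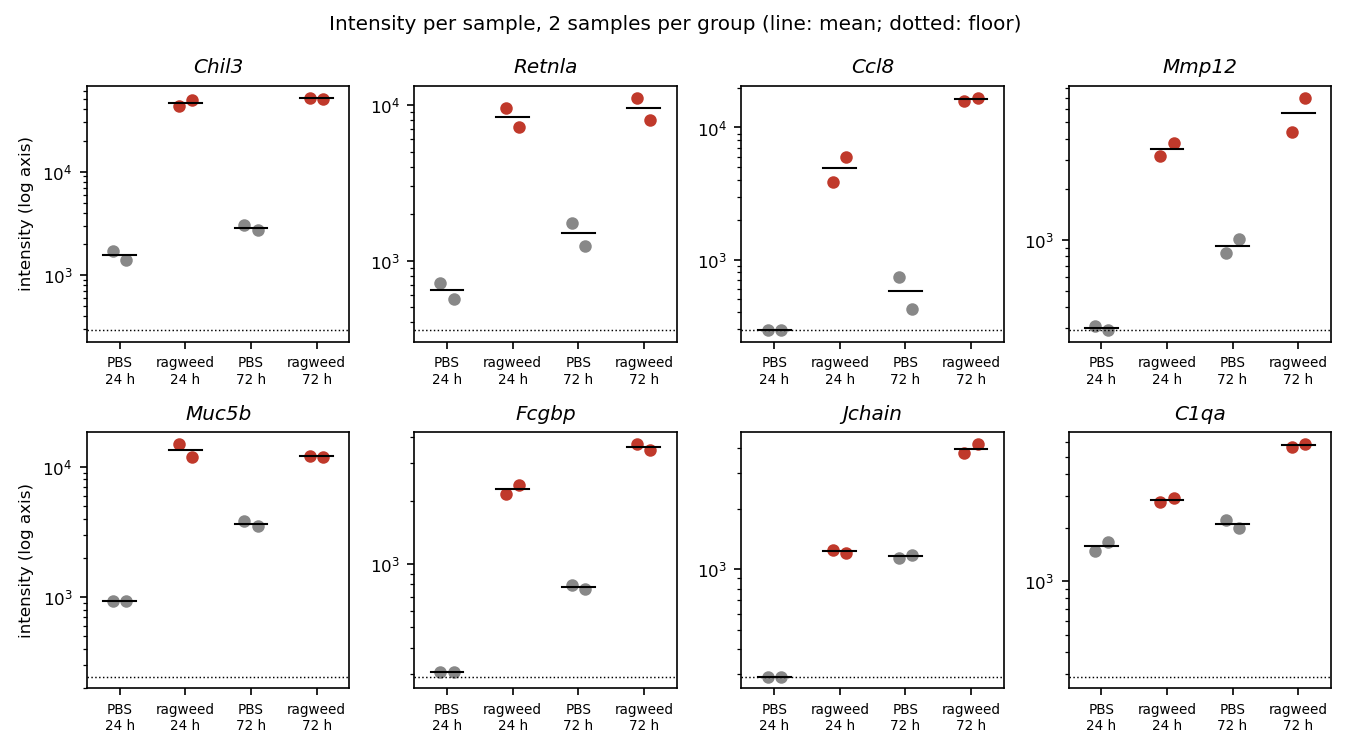
Array intensity on a log axis of Chil3, Retnla, Ccl8, Mmp12, Muc5b, Fcgbp, Jchain and C1qa in each sample of the 4 groups. Points are samples, lines are group means and the dotted line is the floor. Mean Chil3 intensity was 1544 and 2876 in the PBS groups and 46647 and 51506 in the ragweed groups at 24 h and 72 h.

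At 72 h the mucus and alternatively activated macrophage genes remained higher in ragweed lungs, and genes of B and plasma cells and of lysosomes were higher too, as were the chemokine Ccl8 and the complement gene C1qb. Striated muscle genes and the squamous epithelium genes Lce3a, Sbsn and Krt4 were lower. Ccl8 rose by 4.88 ± 0.28 (adjusted p = 6.73e-04), from a mean intensity of 580 to 16402, and Chil3 by 4.16 ± 0.12 (adjusted p = 1.05e-05). The ragweed values of Chil3, 52066 and 50946, equal those that the normalization gives to ranks 5 and 6, so rank sets them. On version 2 A Chil3 rose by 3.18 ± 0.21. Retnla rose by 2.69 ± 0.25 (adjusted p = 0.00105), Mmp12 by 2.59 ± 0.23 (adjusted p = 0.00354) and Ccl9 by 2.29 ± 0.32 (adjusted p = 0.0261). Mzb1 (111469_at), an endoplasmic reticulum protein of plasma cells and marginal zone B cells, rose by 2.96 ± 0.47 (adjusted p = 0.0185). C1qb (96020_at), a chain of the first complement component made by macrophages, rose by 2.45 ± 0.33 (adjusted p = 0.0217). Of the 25250 probe sets, 133 were called, 84 higher and 49 lower, with 2431 at an unadjusted p under 0.05. They gave 48 genes that rose and 35 that fell. Of the 133, 101 were on A, 16 on B and 16 on C. Adjusted within each table, 106 of the 133 were still called, including all 101 on A. Most calls on B and C therefore rest on pooling the tables. Among the genes named for 72 h, Mzb1, Lctl, Cysrt1, Fam25c, Vasn and Sbsn were measured on B, and Spata17, Lce3a and Cldn12 on C.

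Among the largest rises at 72 h were the immunoglobulin variable genes Igkv6-14 (2.51 ± 0.19, adjusted p = 0.00137, 1 of 2 probe sets higher) and Ighv1-54 (2.29 ± 0.32, adjusted p = 0.0233). Fer1l6 rose by at least 3.03 ± 0.40 (adjusted p = 0.0175), Lctl, a klotho-related membrane protein, by 2.40 ± 0.39 (adjusted p = 0.0209) and Spata17 by 2.35 ± 0.39 (adjusted p = 0.0452). On the first-version B array the difference for Lctl was -0.31. The largest falls were in Lce3a (165497_i_at), a late cornified envelope protein, by 2.45 ± 0.32 (adjusted p = 0.0168), and Cysrt1 (113994_at), by at least 1.99 ± 0.32 (adjusted p = 0.0203). Fam25c fell by 1.82 ± 0.21 (adjusted p = 0.00354), Vasn, a membrane protein that binds TGF-beta, by 1.77 ± 0.28 (adjusted p = 0.0182), and Sbsn, suprabasin of stratified epithelium, by 1.62 ± 0.27 (adjusted p = 0.0247). Krt4 (100421_at), a keratin of non-cornified squamous epithelium, fell by 1.47 ± 0.13 (adjusted p = 0.00357), Nppa (103593_at), the atrial natriuretic peptide, by 1.48 ± 0.14 (adjusted p = 0.00399), and Cldn12, a tight junction protein, by 1.45 ± 0.21 (adjusted p = 0.0264). Mean Krt4 intensity was 7412 in PBS and 8988 in ragweed at 24 h, and 24722 in PBS and 8999 in ragweed at 72 h. Against the PBS samples of 24 h its difference was 0.28. Against the same samples the difference was 0.00 for Cysrt1, -0.23 for Lce3a, -0.37 for Fam25c, -0.60 for Sbsn and -0.67 for Nppa, none called, so much or all of these falls rests on the PBS samples of 72 h. It was -1.64 for Vasn and -1.69 for Cldn12, both called. The rise of Spata17 was not called there (0.86).

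At 72 h, 16 of the 37 lists passed, 13 upward and 3 downward, and 5 passed with an estimated correlation. Those 5 were mucous, alternatively activated macrophage, B and plasma cell, lysosomal and striated muscle genes. Of 13 mucous and goblet cell genes, 6 rose, with 9 higher when adjusted over the list alone (median 1.01, list adjusted p = 4.65e-13), among them Tff2, a trefoil peptide of mucus (2.23 ± 0.18), Fcgbp (2.20 ± 0.16), Bpifb1 (1.77 ± 0.22) and Agr2 (at least 1.76 ± 0.26). Of 14 alternatively activated macrophage genes, 3 rose, with 8 higher when adjusted over the list alone (median 0.89, list adjusted p = 2.96e-08). Of 17 B cell and plasma cell markers, 4 rose, with 10 higher and 1 lower when adjusted over the list alone (median 0.70, list adjusted p = 3.57e-08). They included Jchain (1.78 ± 0.17), Ighm (1.75 ± 0.12, 10 of 12 probe sets higher) and Cd22, an inhibitory B cell receptor (1.38 ± 0.20). Of 17 lysosomal proteases and hydrolases, 3 rose, with 7 higher when adjusted over the list alone (list adjusted p = 2.32e-07): Ctss (1.23 ± 0.09), Ctsz (1.02 ± 0.14) and Ctsb (0.88 ± 0.09).

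Of 16 heart and skeletal muscle markers, 2 fell at 72 h, Nppa and Myl7, an atrial myosin light chain (-1.31 ± 0.17), and 10 were lower when adjusted over the list alone (median -0.64, list adjusted p = 5.47e-08). Against the PBS samples of 24 h the list went upward (list adjusted p = 0.118), and against the PBS samples of both times the list adjusted p was 0.114. In the PBS 72 h samples the ratio of 3' to 5' actin signal on the version 2 A array was 0.189 and 0.198, against 0.535 and 0.437 in PBS at 24 h and 0.801 and 0.578 in ragweed at 72 h. On the first-version A array this ratio lay between 0.798 and 0.968.

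The other 11 lists that passed at 72 h did so with the preset correlation. Of 10 eosinophil and T helper 2 chemokines, 2 rose, Ccl8 and Ccl9, with 4 higher when adjusted over the list alone (list adjusted p = 4.63e-06; adjusted p = 0.0725 with an estimated correlation). Of 14 macrophage and monocyte markers, 2 rose, with 4 higher when adjusted over the list alone (list adjusted p = 2.73e-04; adjusted p = 0.0725 with an estimated correlation). Mpeg1, the macrophage perforin, rose by 1.38 ± 0.23. Of 11 MHC class II genes, H2-Aa rose by 0.73 ± 0.09, with 7 higher when adjusted over the list alone (list adjusted p = 0.00242; adjusted p = 0.0922 with an estimated correlation). Pigr, by 1.40 ± 0.10, was the riser among 8 Fc and immunoglobulin receptors, with 3 higher when adjusted over the list alone (list adjusted p = 0.00242; adjusted p = 0.0922 with an estimated correlation). Of 13 complement genes, 2 rose, C1qb and C1qa (1.46 ± 0.11), with 4 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.00281; adjusted p = 0.158 with an estimated correlation). Of 20 genes for protein folding and secretion in the endoplasmic reticulum, none was called and 4 were higher when adjusted over the list alone (list adjusted p = 9.18e-04; adjusted p = 0.118 with an estimated correlation). Against the PBS samples of 24 h this list went the other way (list adjusted p = 0.00395), and against those of both times it did not pass (0.840).

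Of 20 cytochrome P450 and other xenobiotic metabolism genes, 1 rose and 2 fell at 72 h, with 1 higher and 5 lower when adjusted over the list alone (median -0.31, list adjusted p = 0.00170; adjusted p = 0.0922 with an estimated correlation). Gsto1, a glutathione transferase, rose by 1.23 ± 0.13, Cyp2f2 fell by 0.81 ± 0.09 and Gstm1 fell by 0.68 ± 0.10, with 2 of its 4 probe sets lower. For Cyp2f2 the difference was 0.87 against the PBS samples of 24 h and 0.20 on the version 2 A array. The list adjusted p was 0.161 against the PBS samples of 24 h and 0.0592 with the other array version. The remaining 4 lists rested on genes below the threshold. They were interferon response (2 of 21 higher when adjusted over the list alone, list adjusted p = 0.00668; adjusted p = 0.346 with an estimated correlation), acute phase (4 higher and 1 lower of 12, 0.0102; adjusted p = 0.118 with an estimated correlation), fat cell markers, which went down (1 higher and 3 lower of 6, 0.0175; adjusted p = 0.145 with an estimated correlation), and neutrophil and interferon-induced chemokines (2 of 5, 0.0465; adjusted p = 0.385 with an estimated correlation). Without ragweed 72 h 1b the list adjusted p was 0.121 for complement, 0.0583 for interferon response, 0.0511 for fat cells and 0.0767 for the neutrophil chemokines. Without ragweed 72 h 1a it was 0.0645 for acute phase and 0.115 for the neutrophil chemokines, and without PBS 72 h 1b it was 0.152 for acute phase, 0.0991 for fat cells and 0.150 for the neutrophil chemokines. Without the ragweed 24 h 1a or 1b sample it was 0.0581 or 0.0579 for the neutrophil chemokines. With the other array version it was 0.144 for fat cells, 0.395 for acute phase, 0.0904 for the neutrophil chemokines and 0.947 for interferon response, which went downward. Fat cell markers went upward against the PBS samples of 24 h (0.0776), and did not pass against those of both times (0.706).

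Several lists held called members at 72 h without passing. Of 30 cell cycle genes, Aurkb, a mitotic kinase, rose by 1.32 ± 0.20 (list adjusted p = 0.0553), though its difference on the version 2 A array was -0.20. Of 25 extracellular matrix and remodelling genes, 2 rose and 2 fell (list adjusted p = 0.967; median -0.03, mean and test upward). Sparc, a matrix glycoprotein, fell by 0.89 ± 0.10 and Col1a1, a fibrillar collagen chain, by 0.64 ± 0.10, while Col1a1 differed by 0.17 on version 2 A. Of 10 smooth muscle and pericyte markers, Acta2, smooth muscle actin, rose by 0.86 ± 0.13 and Notch3, a receptor of mural cells, fell by 1.23 ± 0.16 (list adjusted p = 0.256). Ramp2, the adrenomedullin coreceptor of endothelium, fell by 0.65 ± 0.10 among 17 endothelial cell markers (list adjusted p = 0.103). Reg3g rose by 1.55 ± 0.19, and Sat1, which acetylates polyamines, by 1.12 ± 0.14. The 72 h differences were at least 1.18 for Arg1 (adjusted p = 0.122), 0.81 for Ccl11 (adjusted p = 0.421), 1.25 for Ccl24 (adjusted p = 0.302), at least 0.97 for Clca1 (adjusted p = 0.151) and 0.99 for Itln1 (adjusted p = 0.160). They were 0.10 for Il5, with 1 of its 4 values above the floor, 0.10 for Il4ra, 0.31 for Ccl22, -0.62 for Mcpt1, -0.09 for Scgb1a1 and 0.06 for Sftpc, none called. On version 2 A they were 0.88 for Scgb1a1 and at least 0.69 for Mcpt1, not called either. Markers of eosinophils (3 measured, list adjusted p = 0.274), T cells (12, 0.790; median 0.05, mean and test downward) and neutrophils (8, 0.518; median 0.03, mean and test downward) did not pass.

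The 72 h count fell to 4 and 4 without PBS 72 h 1a or 1b, 16 without ragweed 72 h 1a and 2 without ragweed 72 h 1b. It was 54 and 59 without a PBS 24 h sample and 42 and 42 without a ragweed 24 h sample. Of the 46 called genes named for 72 h, all kept their direction in these fits, and Chil3 passed in every one. Their kept direction was largely fixed by their choice and is no support. Against the PBS samples of 24 h, 33 of the 46 were still called in the same direction, Cyp2f2 was called in the opposite one and 12 were not called.

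**Figure D2:**
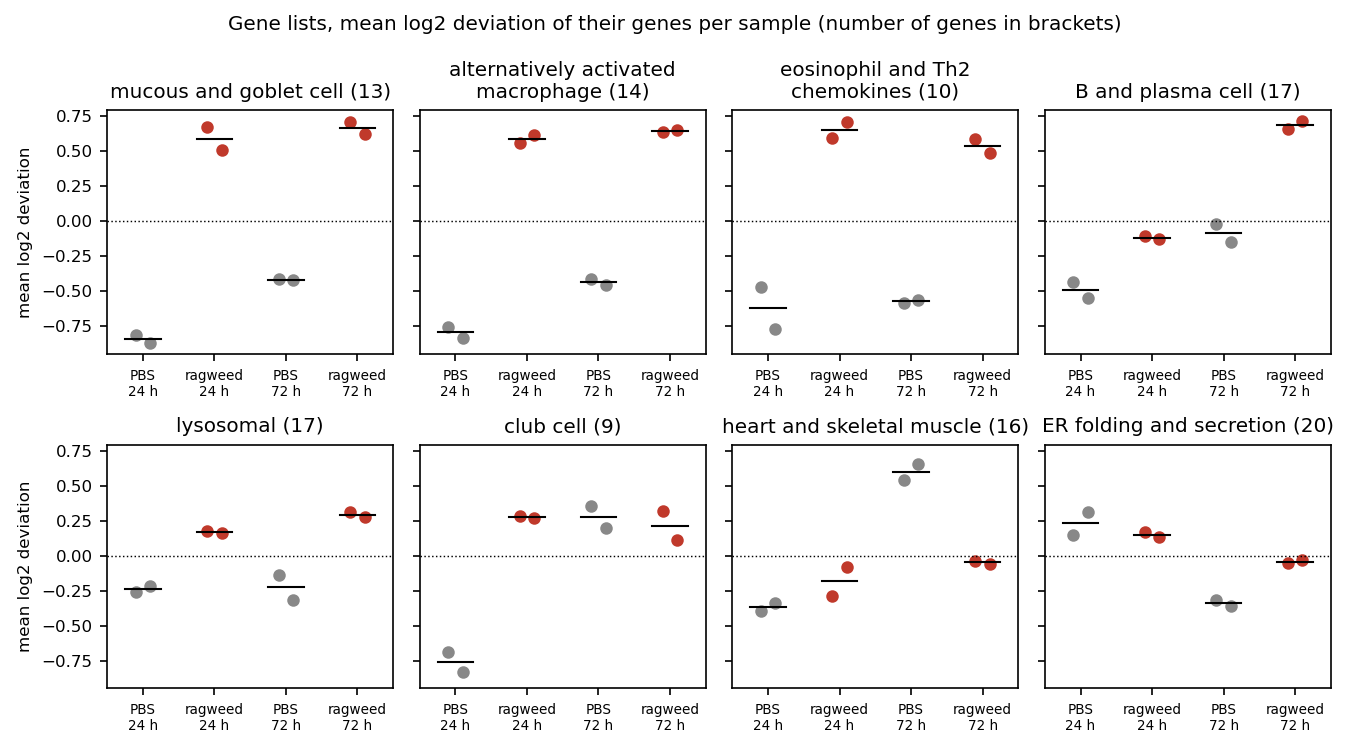
Mean log2 deviation of the measured members of 8 gene lists in each sample of the 4 groups, each gene centred on its mean over the 8 samples. Points are samples and lines are group means. Mucous, alternatively activated macrophage and chemokine genes were higher in both ragweed groups, and club cell and muscle genes were lower in PBS at 24 h than in PBS at 72 h.

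The rises at 24 h and 72 h overlapped. Of 53 probe sets that rose at 24 h and 84 that rose at 72 h, 31 were shared. The groups compared share no arrays, but both tests take their variance from the same 8 arrays, which links their calls. Of the 5 and 49 that fell, 0 were shared in limma, where 2190 and 2431 probe sets had an unadjusted p under 0.05. Across all 25250 tested probe sets the effects at the 2 times correlated with r = 0.147 and rho = 0.126. Across the 158 called at either time, which were chosen by their effects, the values were r = 0.433 and rho = 0.422, and 111 had the same direction. These are correlations across probe sets, which are not independent replicates.

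Over the mean of both times, Chil3 was 4.54 ± 0.09 higher in ragweed (adjusted p = 3.05e-07), with the limit that rank sets its ragweed values. Ccl8 was at least 4.46 ± 0.19 higher (adjusted p = 3.89e-05), a bound because PBS at 24 h lay at the floor. Retnla was 3.19 ± 0.18 higher (adjusted p = 1.67e-05). Arg1 rose by at least 1.80 ± 0.17 (adjusted p = 0.00334), Ccl11 by 1.65 ± 0.21 (adjusted p = 0.0177), Itln1, a lectin of goblet cells, by 0.98 ± 0.16 (adjusted p = 0.0464) and Scgb1a1 by 0.59 ± 0.08 (adjusted p = 0.0239). The value of Scgb1a1 is set by its rank, and its difference was 1.27 at 24 h and -0.09 at 72 h. The mean contrast called 164 probe sets, 117 higher and 47 lower, with 80 genes that rose and 38 that fell. Leaving out 1 sample gave 59 (PBS 24 h 1a), 52 (PBS 24 h 1b), 106 (ragweed 24 h 1a), 42 (ragweed 24 h 1b), 49 (PBS 72 h 1a), 39 (PBS 72 h 1b), 47 (ragweed 72 h 1a) and 48 (ragweed 72 h 1b). Of 45 called genes named for this contrast, 17 passed in every one of these fits, among them Chil3, Ccl8, Retnla, Mmp12, Muc5b, Fcgbp, Agr2, Jchain, Ighm, Pigr, Ctss, Ctsb and C1qa.

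**Figure D3:**
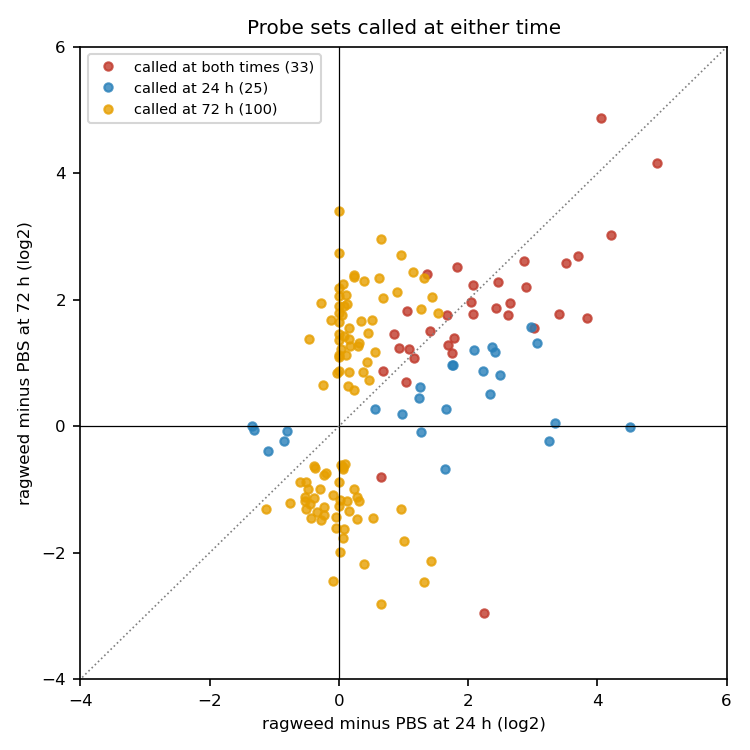
Log2 difference between ragweed and PBS at 72 h (vertical axis) against that at 24 h (horizontal axis) for the 158 probe sets called at either time. Colours mark the 33 called at both times, the 25 called at 24 h and the 100 called at 72 h.

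The difference between ragweed and PBS changed between 24 h and 72 h for few genes, among them keratins of squamous epithelium, a muscle actin and a club cell enzyme. For Krt4, Acta1 and Cyp2f2 the PBS groups differed between the times, by 1.74, 1.94 and 1.68 (72 h minus 24 h). The ragweed groups differed by -0.0038, -0.38 and 0.22, none called. Between the ragweed times Krt13 (164542_f_at), Fam25c and Ighm 101870_at were called. In this test of the difference itself, 9 probe sets were called, 1 higher and 8 lower at 72 h, with 1857 at an unadjusted p under 0.05. Krt13 (164542_f_at), a keratin of squamous epithelium, changed from at least 2.24 higher at 24 h to at least 2.96 lower at 72 h, a difference of -5.20 ± 0.49 (adjusted p = 0.00309), with PBS at 24 h and ragweed at 72 h at the floor. Another probe set of Krt13, on the A array, gave -0.23 at 24 h and -1.40 at 72 h, a difference of -1.17 ± 0.19 (adjusted p = 0.163, not called). Krt4 differed by -1.75 ± 0.19 (adjusted p = 0.0350) and Fam25c by -2.83 ± 0.30 (adjusted p = 0.00556). Acta1 (100381_at), skeletal muscle actin, was 1.64 higher at 24 h and 0.68 lower at 72 h, a difference of -2.31 ± 0.18 (adjusted p = 0.00556). Cyp2f2 (100069_at) differed by -1.46 ± 0.13 (adjusted p = 0.00868). One probe set of Ighm (101870_at) was higher at 72 h, with a difference of 3.41 ± 0.29 (adjusted p = 0.00868). It lay at the floor in both groups of 24 h. The floored groups of Krt13 164542_f_at and Ighm 101870_at add no spread, so the errors and p-values of both may be too small. The other 3 probe sets, each matched to more than 1 gene, were 101024_i_at (-4.51 ± 0.31), 101025_f_at (-3.31 ± 0.21) and 93028_at (-2.28 ± 0.21). Krt13, Ighm 101870_at and these 3 lie outside the naming rule and were chosen after their values were seen.

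Chil3, Ccl8, Arg1, Ccl11 and Scgb1a1 were not called for a difference between the times. Chil3 differed by -0.76 (adjusted p = 0.394), Ccl8 by 0.83 (adjusted p = 0.711), Arg1 by -1.23 (adjusted p = 0.517) and Ccl11 by -1.68 (adjusted p = 0.467). Scgb1a1, whose rank sets its value, differed by -1.35 (adjusted p = 0.0628). Most simulated changes were missed even at a single time, so this does not show that the effects were alike at both times. Of 9 club cell markers, 1 fell, with 7 lower when adjusted over the list alone (median -1.19, list adjusted p = 2.62e-09; adjusted p = 0.0930 with an estimated correlation). Of 16 heart and skeletal muscle markers, 1 fell, with 5 lower when adjusted over the list alone (median -0.54, list adjusted p = 3.50e-06; adjusted p = 0.0930 with an estimated correlation). Endoplasmic reticulum folding genes had no called member and 5 of 20 higher when adjusted over the list alone (median 0.36, list adjusted p = 0.00201; adjusted p = 0.299 with an estimated correlation). Mucous and goblet cell genes had no called member, with 1 higher and 2 lower of 13 when adjusted over the list alone (median -0.36, list adjusted p = 0.0408; adjusted p = 0.299 with an estimated correlation). The mucous list did not pass without PBS 24 h 1b (0.0993), ragweed 24 h 1a (0.0943), PBS 72 h 1a or 1b (0.0654 or 0.0556), or ragweed 72 h 1a or 1b (0.105 or 0.179). Of the 9 probe sets, 8 were also called between the PBS groups and 3 between the ragweed groups. The number called was 5 without PBS 24 h 1a, 1 without PBS 24 h 1b, and 0 in limma without any other sample, where 1920 to 2451 had an unadjusted p under 0.05.

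PBS lungs of 72 h differed from PBS lungs of 24 h in club cell and striated muscle genes as groups, and in single squamous epithelium, immunoglobulin and protein folding genes. Cyp2f2 was 1.68 ± 0.09 higher at 72 h (adjusted p = 6.55e-04) and Scgb3a2 (165031_at), a club cell secretoglobin, 2.03 ± 0.30 (adjusted p = 0.0164). Scgb1a1 was 1.27 ± 0.12 higher (adjusted p = 0.00570) on the first-version A array, where its rank sets its value, and -0.63 on version 2 A. Acta1 was 1.94 ± 0.13 higher (adjusted p = 0.00130) and Lce3a 2.22 ± 0.32 (adjusted p = 0.0357). Igkv6-23 (102156_f_at), a light chain variable gene, was 2.57 ± 0.12 higher (adjusted p = 3.57e-04), Jchain at least 1.99 ± 0.17 (adjusted p = 0.00429), and Slc35a4 at least 2.71 ± 0.36 (adjusted p = 0.0108, 1 of 2 probe sets higher). The log2 difference was at most -2.79 ± 0.39 for Slc7a11 (116709_at), the cystine transporter (adjusted p = 0.0120), -1.91 ± 0.23 for Uchl1, a ubiquitin hydrolase (adjusted p = 0.0164), and -1.83 ± 0.22 for Adam28 (adjusted p = 0.0164), all bounds. It was -1.52 ± 0.26 for Blvrb, biliverdin reductase B (adjusted p = 0.0410), and -1.48 ± 0.13 for Krt8, a keratin of simple epithelium (adjusted p = 0.00542). In total 71 probe sets were called, 47 higher and 24 lower at 72 h, with 2107 at an unadjusted p under 0.05. On version 2 A the difference was 0.31 for Adam28.

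Of the 37 lists, 10 passed between the PBS groups, 9 upward and 1 downward, and 2 of these passed with an estimated correlation. Of 16 heart and skeletal muscle markers, 1 rose, with 12 higher when adjusted over the list alone (median 0.93, list adjusted p = 4.85e-13). Of 9 club cell markers, 5 rose, with 6 higher when adjusted over the list alone (median 1.27, list adjusted p = 1.44e-11; median 1.18 without Scgb1a1). Of 20 endoplasmic reticulum folding genes, 3 fell, with 11 lower when adjusted over the list alone (median -0.56, list adjusted p = 3.07e-09; adjusted p = 0.0595 with an estimated correlation): Manf, a stress-induced secreted factor (-1.42 ± 0.16), Hspa5, the main chaperone of that compartment (-1.25 ± 0.16), and Pdia6, a disulfide isomerase (-1.19 ± 0.14), which differed by 0.28 on version 2 A. MHC class II genes passed upward with 1 riser of 11 and 3 higher when adjusted over the list alone (list adjusted p = 6.02e-06; adjusted p = 0.0595 with an estimated correlation). Fat cell markers passed upward with 1 riser of 6, Ucp1, the uncoupling protein of brown fat (at least 1.85 ± 0.24), and 3 higher when adjusted over the list alone (list adjusted p = 2.04e-04; adjusted p = 0.0938 with an estimated correlation). B and plasma cell, mucous and alternatively activated macrophage genes passed upward with 2 risers each and 5, 4 and 3 higher when adjusted over the list alone. Their list adjusted p values were 0.00109, 0.00120 and 0.00515 (adjusted p = 0.111, 0.108 and 0.119 with an estimated correlation). Without PBS 72 h 1a the B and plasma cell list had an adjusted p of 0.0535, and with the other array version the macrophage list had 0.118. Muc5b rose by 1.97 ± 0.18, Fcgbp by 1.35 ± 0.16, Mmp12 by 1.62 ± 0.23 and Chil3 by 0.90 ± 0.12. Homeostatic lymphoid chemokines and complement passed with no called member (list adjusted p = 0.0221 and 0.0343; adjusted p = 0.190 and 0.393 with an estimated correlation). The chemokine list did not pass without PBS 24 h 1a (0.0527) or PBS 72 h 1a or 1b (0.0557 or 0.0636), nor complement without PBS 24 h 1a or 1b (0.0527 or 0.0842) or PBS 72 h 1a (0.242).

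The PBS count was 0 in limma without PBS 72 h 1a or 1b, with 2256 and 1973 at an unadjusted p under 0.05. It was 11 and 10 without PBS 24 h 1a or 1b, 20 and 16 without ragweed 24 h 1a or 1b, and 4 and 9 without ragweed 72 h 1a or 1b. None of the 26 called genes named for it passed in every one of these fits, and all 26 kept their direction.

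The version 2 A array repeated the 72 h comparison on the same samples, and carries genes that were not tested elsewhere. Chia1, the acidic chitinase, rose there from a mean intensity of 1536 to 17727, by 3.54 ± 0.16 (adjusted p = 7.86e-04). Chil3 rose by 3.18 ± 0.21, Ccl8 by 5.66 ± 0.33, Itln1 by 2.25 ± 0.26 (adjusted p = 0.0149), Arg1 by at least 1.98 ± 0.19 (adjusted p = 0.00616) and Ccl11 by at least 1.90 ± 0.19 (adjusted p = 0.00660). Clca1, a goblet cell protein induced by interleukin 13, rose by 5.07 ± 0.74 (adjusted p = 0.0260), against at least 0.97 for another probe set on the first version. Muc5ac, an inducible airway mucin, differed by at least 0.62 ± 0.20 (adjusted p = 0.185). Sftpc, a surfactant protein, rose by 3.74 ± 0.52 (adjusted p = 0.0215), against 0.06 for the same probe set on the first version, where its rank sets its value and the difference is no measure of it. Sftpc was 2.53 lower in PBS at 72 h than in PBS at 24 h on version 2 A (adjusted p = 0.0907), so much of its rise rests on the PBS 72 h samples, and Sftpb, another surfactant protein, differed by 0.10 between ragweed and PBS. Krt4 differed by -0.70 (adjusted p = 0.0537) and Reg3g by 0.29 (adjusted p = 0.504). Across 6283 probe sets shared by the A versions, the 72 h effects correlated with r = 0.394 and rho = 0.205, across probe sets. Adjusted within each table, 190 were called on the first version and 143 on version 2, with 73 on both, and 163 of the 190 had the same direction on version 2. The first-version and version 2 B arrays repeated less, with r = 0.135 at 24 h and 0.0661 at 72 h across 6764 shared probe sets, and so did the C arrays, with r = 0.0144 and 0.113 across 4239. On B and C, 0 to 3 probe sets were called per table and at most 1 on both versions. Between the PBS groups the correlation was 0.417 on A, 0.143 on B and 0.0515 on C.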

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

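The tests of striated muscle markers, of the scale of the first-version arrays, of the share of airway and of a ceiling or scale of bright probe sets were chosen after the results were seen. A test of the difference between the ragweed effects at 72 h and 24 h (72 h minus 24 h) drew attention to 9 probe sets and 4 gene lists. The log2 differences were -5.20 for Krt13, -1.75 for Krt4, -2.83 for Fam25c, -2.31 for Acta1, -1.46 for Cyp2f2 and 3.41 for Ighm 101870_at. They were -4.51 for 101024_i_at, -3.31 for 101025_f_at and -2.28 for 93028_at, each matched to more than 1 gene. The list medians were -1.19 for club cell markers, -0.54 for heart and skeletal muscle markers, 0.36 for protein folding and secretion in the endoplasmic reticulum and -0.36 for mucous and goblet cell genes. Of the 9 probe sets, 8 were also called between the PBS groups, which share arrays with this test, and 3 between the ragweed groups.

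Some squamous epithelium transcripts and most striated muscle markers were higher in PBS at 72 h than in PBS at 24 h and ragweed at 72 h, with 17 of 31 measured squamous markers higher and 14 lower between the PBS groups (median 0.11, 4 called here or on version 2 A, camera p = 4.31e-04 and 0.0234 with an estimated correlation). Version 2 A argues against the scale of the first-version arrays as the whole cause of the difference from PBS at 24 h. All arrays share 1 scale there, and 87 of 95 probe sets called between the PBS groups went the same way. Both PBS groups were unscaled on the first version, so this count does not cover the difference from ragweed at 72 h. For that difference 163 of 190 called probe sets went the same way on version 2 A. These are all calls at 72 h, rises included, and not squamous and muscle genes alone. On version 2 A, 13 of 14 muscle and 16 of 20 squamous markers were lower in ragweed. With an estimated correlation camera p was 0.0785 and 0.0937. The actin ratios of 3' to 5' signal in PBS at 72 h were low there (0.189 and 0.198). Heart or skeletal muscle in the PBS 72 h samples remains a candidate explanation: 100% of the 14 muscle markers measured on version 2 A were higher there, and 15 of 16 on the main tables, though Acta1 stood apart in PBS at 24 h instead (mean intensity 2205, against 8395 in PBS at 72 h and 6871 and 5257 in ragweed). These counts restate the pattern, and version 2 A measured the same samples. They do not tell muscle tissue from any other cause of the rise. The camera p of the muscle list with an estimated correlation was 0.00117 on the main tables and 0.0642 on version 2 A. The PBS 72 h samples scored 0.44 and 1.11 on version 2 A. Fat cell markers scored 0.42 and 0.68 against -0.29 and -0.40 in PBS at 24 h on the main tables (list adjusted p = 2.04e-04; adjusted p = 0.0938 with an estimated correlation), but -0.09 and 1.29 against -0.28 and -0.45 on version 2 A (camera p = 0.293 with an estimated correlation), which rests mostly on 1 sample, and whether the muscle lay inside or outside the lung was not tested. Squamous tissue other than lung stays open. The 27 measured squamous markers outside the called ones (41 listed in all, 1 of them also in a fixed list) had a median of -0.0130 (SE 0.13, camera p = 0.0672), with 13 higher and 14 lower. This median lay below the limit set for arguing against squamous tissue, but by less than its SE. The squamous list is not one of the fixed lists. Its markers outside the called ones could be picked only after the PBS groups had been compared. A difference between PBS lungs of 24 h and 72 h stays open too, since it was not tested apart from squamous tissue.

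Club cell genes were lower in PBS at 24 h than in PBS at 72 h and in ragweed at 24 h. On the main tables, less airway in the PBS 24 h samples is argued against for ciliated cells alone, by the 6 markers measured. Their median difference was -0.0827 (SE 0.12) beside 1.27 (SE 0.28) for club cell markers and 1.18 (SE 0.32) without Scgb1a1. On version 2 A the medians were -0.0252 (SE 0.0757) for 4 ciliated and 0.36 (SE 0.40) for 7 club cell markers, which does not tell them apart. Mucous and goblet cell genes, among them the airway mucin Muc5b, were lower in PBS at 24 h as a list. Their median was 0.19 on the main tables, with 7 higher and 6 lower (camera p = 2.26e-04, and 0.0175 with an estimated correlation). On version 2 A it was 0.38, with 8 higher and 3 lower. Less airway in the PBS 24 h samples therefore stays open. A ceiling or scale effect on bright probe sets may contribute and stays open, since the median of the 7 club cell markers measured on version 2 A was 0.36 (SE 0.40), and 0.51 (SE 0.41) without Scgb1a1. A lasting effect of the intratracheal challenge on club cells at 24 h is a biological hypothesis that was not tested by itself. The ragweed 24 h samples had the same route and time of challenge. Their club cell scores on the main tables were 0.28 and 0.27. PBS scored -0.69 and -0.83 at 24 h, and 0.35 and 0.19 at 72 h. For these samples the scores argue against an effect of the procedure alone, unless ragweed offset it.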

How the results depend on the processing

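The alternatives with flooring before scaling, the first-version A table alone, no C table, and PBS samples of both or of the other time were chosen after the data were seen. An additional ragweed 24 h sample, planned on the first-version A array, was not run, since that array repeats the 1a array. Leaving out 1 sample leaves its group with 1, which is assumed to vary like the others. It gave 22 to 204 called probe sets at 24 h (58 with all samples), 2 to 59 at 72 h (133), 39 to 106 for the mean (164), 0 to 5 for the difference (9) and 0 to 20 between the PBS groups (71). Lists passing ranged from 9 to 13 at 24 h, 13 to 16 at 72 h and 3 to 5 for the difference. Between 56.4 and 60.7% of the values of a version 2 B or C array lay above the floor, and lower values give bounds at most. The median standard error was 0.45 on C against 0.23 on A, and the cause was not tested. With the replicate block the counts were 58, 90, 120, 8 and 59, and 10, 15 and 3 lists passed; the codes do not pair the samples (r of residuals across groups from -0.0790 to 0.0438).

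At 24 h, 98 were called with an offset, 121 without a filter, 101 with a filter on 4 arrays, 91 adjusted within each table, and 0 in limma with only the 2 groups of the contrast (2289 at an unadjusted p under 0.05), which leaves fewer samples. Of the 91, 51 were among the 58, including all 44 of the 58 that were on A. With PBS samples of the other time 81 were called (46 higher and 35 lower), 32 of them among the 58. At 72 h, 64 were called with the other array version, 80 without the trend, 2 with only the groups of the contrast, 238 with PBS of both times and 236 with PBS of the other time. For the mean, 256 were called with the filter on 4 arrays, 98 without the trend, 248 adjusted within tables and 258 floored before scaling. For the difference, 14 were called with the floor at the 60th percentile, 21 with an offset, 123 without a filter, 20 with the filter on 4 arrays, 4 without the trend, 23 adjusted within tables and 21 on the A table alone. Between the PBS groups, 41 were called with the other version, 118 without a filter, 107 with the filter on 4 arrays, 32 without the trend and 0 in limma with only the groups of the contrast (2450 unadjusted). With an estimated correlation 5 lists passed at 72 h and 0 for the difference (11 at an unadjusted p under 0.05 with the preset correlation, limma). The difference had 8 with the other version and 8 without the C table. The correlation of the A versions at 72 h was 0.240 with the floor at the 20th percentile and 0.856 among called probe sets. Apart from the smaller number of samples, the cause was not tested.

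Directions reversed or reached 0 as follows, and the cause was not tested; Scgb1a1 and Hp at 72 h were not called with their own PBS samples (-0.09 and -0.41). With PBS samples of the other time, the 24 h values were 0.0344 for Srxn1, 0.0329 for Krt19, 0.18 for Sqstm1, 0 for Scgb1a1, -0.00727 for H2-DMb1, -1.03 for Cyp2f2 and -0.30 for Acta1, and the 72 h values 0.28 for Krt4, 1.18 for Scgb1a1, 0.89 for Hp and 0.87 for Cyp2f2, and 0 for Cysrt1 at 72 h. With PBS of both times Cyp2f2 was -0.19 at 24 h and 0.0289 at 72 h. With the other array version, the 72 h values were -0.31 for Lctl, -0.20 for Aurkb, 0.17 for Col1a1 and 0.20 for Cyp2f2, and the PBS values 0.31 for Adam28, -0.63 for Scgb1a1 and 0.28 for Pdia6. Of 3777 values of called genes under the alternatives, 2503 kept direction and call, 1256 kept direction alone, counting Cysrt1 at 0, and 18 reversed or were 0. Another 77 values changed sign where neither was called and are not listed. The 3777 values include the fits without 1 sample, where a kept direction was largely fixed by the choice of genes.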

Other observations

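The test of tissue handling was chosen after the result was seen. Over the mean of both times, endothelial, alveolar type I and xenobiotic metabolism lists passed downward in ragweed lungs with the preset correlation, and none of the 3 passed with an estimated one. Kdr, the main VEGF receptor of endothelium, fell by 0.78 ± 0.13 (adjusted p = 0.0464) and Cdh5, the cadherin of endothelial junctions, by 0.55 ± 0.09 (adjusted p = 0.0353), while Vwf, von Willebrand factor, rose by 0.48 ± 0.08 (adjusted p = 0.0438). Of 17 endothelial cell markers, 1 rose and 2 fell, with 1 higher and 4 lower when adjusted over the list alone (list adjusted p = 0.0284; adjusted p = 0.147 with an estimated correlation). Of 11 alveolar type I cell markers none was called and 3 were lower when adjusted over the list alone (median -0.22, list adjusted p = 0.0163; adjusted p = 0.272 with an estimated correlation). Of 20 xenobiotic metabolism genes, 1 rose and 1 fell, with 2 higher and 8 lower when adjusted over the list alone (median -0.27, list adjusted p = 0.0161; adjusted p = 0.136 with an estimated correlation). Hpgd, which inactivates prostaglandins, fell by 0.85 ± 0.10 (adjusted p = 0.0135), and Cyp4b1, a lung cytochrome P450, by 0.40 ± 0.06 (adjusted p = 0.0348). Leaving out 1 sample raised the list adjusted p to 0.0733 (PBS 24 h 1a), 0.0807 (ragweed 24 h 1a), 0.0530 (PBS 72 h 1a) and 0.0712 (ragweed 72 h 1a) for endothelial cells, and to 0.107 (PBS 24 h 1a), 0.113 (ragweed 24 h 1b) and 0.0702 (PBS 72 h 1a) for alveolar type I cells. For the xenobiotic list it was 0.103 without PBS 24 h 1b and 0.0504 without PBS 72 h 1a. Median centring gave 0.0530 for the xenobiotic and 0.0712 for the endothelial list. For the endothelial list it was also 0.0507 with the other normalization, 0.0661 with the floor at the 60th percentile and 0.0693 floored before scaling, and for alveolar type I cells 0.0710 on the A table alone. Kdr, Cdh5, Vwf, Hpgd and Cyp4b1 were each not called when any of at least 6 of the 8 samples was left out, and kept their direction. Over all alternatives their adjusted p reached 0.207, 0.195, 0.194, 0.141 and 0.205.

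Several genes of oxidative stress and protein folding were higher in PBS lungs of 24 h than of 72 h (folding list adjusted p = 3.07e-09; adjusted p = 0.0595 with an estimated correlation). The hypothesis that NRF2, the transcription factor of the oxidative stress response, was more active in the PBS 24 h lungs is in line with its target genes outside the called ones, 12 of 17 of which were lower at 72 h (median -0.17, SE 0.17, camera p = 0.00766 and 0.0454 with an estimated correlation). Of the 37 targets listed, 27 were measured, 10 were called between the PBS groups here or on version 2 A and 6 also stand in a fixed list. The median of -0.17 lay beyond the limit set for this hypothesis, but by less than its SE. The NRF2 list is not one of the fixed lists. Its genes outside the called ones could be picked only after the PBS groups had been compared. The same samples gave the pattern and this test, so the test is no independent prediction. Handling of the tissue before RNA extraction may contribute and stays open, since the median of the immediate early and heat shock genes was -0.0891 (SE 0.13). That median met the limit chosen for arguing against handling, but by less than its SE. The time since challenge, which the groups name, was not tested apart from handling.

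Splits of the 8 samples into 4 and 4 were compared by a 2-group limma fit. Ragweed against PBS called 45 probe sets and was 1 of 35 splits with as many, and the highest of the other splits, 24 h against 72 h, called 13. Of the 35 splits, 32 part the samples of a group and 3 keep the groups whole, and 3 splits are too few for a share under 0.05. Ragweed at 72 h against ragweed at 24 h called 77 probe sets, 60 higher and 17 lower.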
